A study of Mus musculus with 6 samples.

How the data were processed

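Gene expression was measured in LSK cells, the lineage-negative, Sca-1-positive and Kit-positive fraction of mouse bone marrow that is enriched in haematopoietic stem cells and early progenitors. Per the labels' protocols, the cells were sorted by flow cytometry, RNA was extracted on columns, and biotin-labelled cRNA was made from 10 ng of total RNA by 2 rounds of amplification. Each of 6 samples was hybridised to 1 single-colour Affymetrix array. The labels put 3 samples in the Gfi1 knockout group and 3 in the wild-type group, numbered 5, 7 and 8 in each. They do not say whether each sample came from 1 mouse or from a pool, so the p-values measure the spread between these samples.

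The values used here are the authors' deposited intensity values, 1 linear signal per probe set and array. MAS5 made them, per the submitters' processing notes, and its version and settings are not given in the sources used here. Each deposited column was already scaled: its mean after trimming 2% of the probe sets from each end lay between 1000.33 and 1000.37, in the arbitrary units of the scanner. No detection calls were used here. With 2 rounds of amplification, signals come mostly from the 3' end of transcripts, and the ratio of the 3' to the 5' Gapdh control probe set was 4.30 to 6.11 over the 6 arrays. For the actin control the same ratio was only 1.15 to 1.47, so the 2 controls differed in how much 3' bias they showed. The number of arrays limits the precision.

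The table held 22690 probe sets. The 64 AFFX control probe sets were left out of all tests, which left 22626. Of these, 20380 had 1 gene symbol in the platform annotation, 691 had several and 1555 had none, and only probe sets with 1 symbol were named. The gene identifiers of 20351 probe sets matched a gene of the RefSeq table of the GRCm38.p6 assembly, which was used for current symbols and for the order of genes along chromosomes only. That match changed 0 symbols. Because the annotation can be old, a probe set may detect other transcripts than its name says.

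From these values, log2(signal + 16) was computed with no further normalization between arrays. The 60% of probe sets with the highest mean over the 6 arrays were tested, 13575 probe sets with a mean signal above about 198. limma 3.58.1 in R 4.3.3 fitted the difference between the groups with lmFit and eBayes (trend = TRUE) over all 6 arrays, two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. All differences are knockout-labelled minus wild-type arrays on the log2(signal + 16) scale, with the standard error (SE) of the fit, and a fold on this scale understates the change of dim probe sets. A second count, which does not rest on the adjusted p, took probe sets that differed by at least 2-fold with every array of one group above every array of the other. As a bound for dim signals, the brightest of 27 control probe sets for Bacillus transcripts was taken on each array (100.2 to 162). A group whose 3 arrays all lay at or below that level has only a bound, and the change is then given as "at least" against the mean of those levels.

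26 gene lists were fixed before the data were examined, from general knowledge of blood cells. They were Gfi1-repressed genes, stem cell genes, the HoxA cluster and its cofactors, lymphoid priming genes, granulocyte-monocyte progenitor genes, megakaryocyte-erythroid genes, MHC class II genes, pro-apoptotic genes, anti-apoptotic genes, p53 target genes, S phase genes, G2 and M phase genes, cell cycle inhibitors, interferon-response genes, immediate early genes, ribosomal protein genes, oxidative phosphorylation genes, sex-linked genes, neighbours of Gfi1, and markers of 7 kinds of other cells that the sort could carry over. Of 783 list entries, 658 matched a probe set with 1 symbol. Each gene was represented by its brightest probe set, and the 25 lists with at least 5 tested genes were tested among 8239 genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. An estimated correlation and fry were alternatives.

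The genes named in the text were chosen by a rule fixed before the data were examined. It took every Gfi1 probe set, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold without overlap between the groups, up to 4 members of each list with the smallest p, and 16 further genes whatever their values, of which 1 is not reported here. A gene was named by its brightest tested probe set. Some genes that the rule took are given only within a list's counts. Genes outside this rule are said to have been chosen after their values were seen.

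The labels' numbers 5, 7 and 8 were checked as a pairing. Deviations from the group means correlated at 0.159, 0.168 and 0.238 between the samples numbered 5, 7 and 8, and between -0.134 and -0.0307 for differently numbered samples of the 2 groups. Because deviations cancel within a group, positive values for same-numbered samples force negative ones elsewhere, which are no separate evidence. The second principal component also ordered the samples by number in both groups. By a rule set beforehand (all pairs above 0.1) the numbers were taken to pair the samples, although no label says what a number stands for. The fit without the number stayed the main one, because no study method asked for such a block. The fit with the number as a block is an alternative. Its value stands beside each named gene or list whose call it changed, and beside each count of calls it moved by over 1.5 times.

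Other alternatives were pseudocounts of 1 and 64, no brightness filter, the brighter 40% of probe sets, median centring, quantile and cyclic loess normalization, eBayes without trend, array weights, leaving out probe sets marked as less specific in their names (_s_at, _x_at and _a_at), and leaving out each array in turn. The procedure was tested on simulated arrays for the comparison of knockout with wild type, with the means and spread of the 13575 tested probe sets and 200 of them changed in each of 5 runs. It called 58% of the probe sets changed 2-fold and 98.8% of those changed 4-fold, 4.02% of its calls were false, and 0 probe sets were called in any run where none was changed. A list shifted by 0.5 on the log2 scale was called in all 5 runs, with at most 1 other list. The simulated noise was independent between probe sets and arrays, with no correlation between genes and no effect of the sample number. These rates hold for such noise only and need not hold for the real lists or calls. Figures were drawn with matplotlib 3.10.9.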

Results

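LSK cells from Gfi1 knockout and wild-type mice were compared to find which transcripts differ across the genome. Gfi1 is a zinc finger transcriptional repressor that acts in haematopoietic stem cells and in granulocyte and lymphoid development. The data were 6 arrays, 3 labelled Gfi1 knockout and 3 wild type, named here by label and sample number. The median signal of an array lay between 285 and 335, and 67.0% to 74.4% of the probe sets of an array were brighter than its brightest Bacillus control. Log2 signals of 2 arrays correlated across probe sets at 0.951 to 0.971 within a group and at 0.927 to 0.955 between the groups. The first principal component, with 40.2% of the variance, parted the groups, and the second, with 20.6%, followed the sample numbers.

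**Figure D1:**
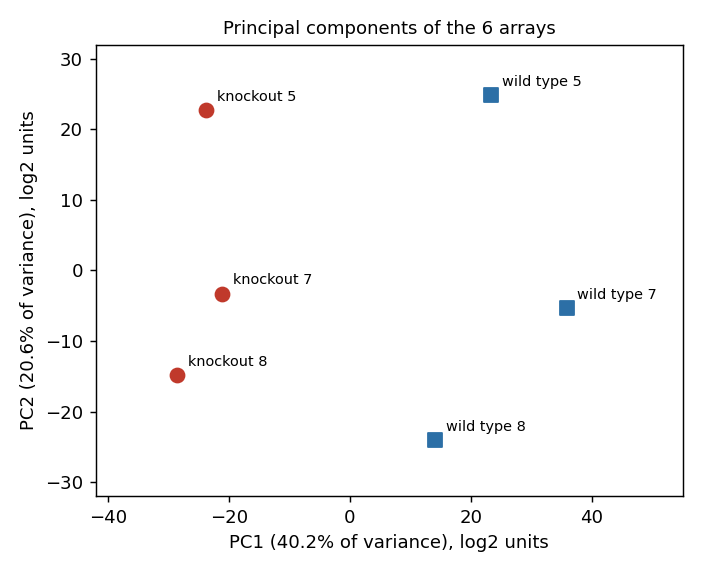
Principal components of the log2(signal + 16) values of the 13575 tested probe sets, 1 point per array, circles for arrays labelled Gfi1 knockout and squares for wild type, with PC1 on the horizontal and PC2 on the vertical axis in log2 units. PC1 (40.2% of the variance) runs from -28.6 to 35.8 and separates the groups, and PC2 (20.6%) places the samples numbered 5 at the top in both groups.

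The targeted gene was not lower on the arrays labelled knockout. Gfi1 had 1 probe set, with signals of 692, 1163 and 1737 on knockout arrays 5, 7 and 8 and of 632, 608 and 723 on wild-type arrays 5, 7 and 8. The group means were 1198 ± 523 and 654 ± 60.4 (SD, n = 3 each), a difference of 0.76 ± 0.28 (SE) on the log2 scale that did not pass the threshold (limma adjusted p = 0.148). Without knockout array 5 the difference was 1.10 with an adjusted p of 0.0354, and over all alternatives the adjusted p for Gfi1 signal ran from 0.0354 to 0.466 (without knockout replicate 8). Whether this probe set lies in the deleted part of the gene is not given in the labels, and a probe set outside it would check nothing. The group is therefore called knockout-labelled in what follows, and every direction rests on those labels.

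The 10 largest rises in the knockout-labelled arrays were Ighg3, Hdc, Igha, Dmkn, Mmp8, Csf2rb2, Ccr2, Csf2rb, Socs3 and Srd5a3. Csf2rb2 and Csf2rb, which encode beta chains of the receptors for IL-3 and GM-CSF, rose by 2.20 ± 0.18 and 2.07 ± 0.23 (SE) on the log2 scale, with mean signals of 7838 ± 1167 against 1690 ± 238 and of 1327 ± 273 against 303 ± 56.3 (SD, n = 3 each). Ccr2, the chemokine receptor of inflammatory monocytes, rose by 2.08 ± 0.29, Mmp8, the neutrophil collagenase, by 2.21 ± 0.25, and Socs3, a feedback inhibitor of cytokine signalling, by 1.94 ± 0.27. Hdc, the enzyme that makes histamine, rose by 2.58 ± 0.52, and its second probe set by 3.56 ± 0.46. The constant regions Ighg3 and Igha differed by 3.12 ± 0.40 and 2.45 ± 0.45, with an SD for Igha on the knockout-labelled arrays of 25959 around a mean of 31678.

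The 10 largest falls were Ddx4, Camp, Oasl2, Myl10, Ngp, Gbp6, Ltf, Gbp8, Myof and Ndn. Ngp, Camp and Ltf encode proteins of neutrophil secondary granules. Ngp fell by 3.37 ± 0.23, from 6627 ± 2330 to 608 ± 107 (SD, n = 3 each), Camp fell by 3.88 ± 0.48 and Ltf fell by 2.38 ± 0.42. Oasl2 and the guanylate-binding protein genes Gbp6 and Gbp8 are induced by interferons. Oasl2 fell by 3.80 ± 0.26, from 2439 ± 888 to 154 ± 13.5, and Gbp8 fell by 2.37 ± 0.45. Gbp6 was at least 5.16-fold lower and Ddx4, an RNA helicase of germ cells, at least 10.2-fold lower, because their 3 knockout-labelled arrays did not exceed the control level. Ndn, a growth suppressor of the MAGE family that is expressed in stem cells, fell by 2.17 ± 0.24. All 3 knockout-labelled arrays lay on one side of all 3 wild-type arrays for each of these 20 genes, and their limma adjusted p-values lay between 8.15e-06 (Oasl2 and Ngp) and 0.0244 (Myof). 15 of the 20 also passed with any 1 array left out. Hdc did not without knockout 7, knockout 8 or wild type 7 (adjusted p up to 0.0982), Igha without knockout 8 (0.0509), Dmkn without knockout 7 or 8 (up to 0.0855), and Gbp8 and Myof without knockout 8 or wild type 7 (up to 0.0857 and 0.122). Without the brightness filter Hdc, Igha, Dmkn, Ltf, Gbp8 and Myof did not pass (adjusted p up to 0.0939), and with eBayes without trend Hdc, Igha and Myof did not (up to 0.0712).

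**Figure D2:**
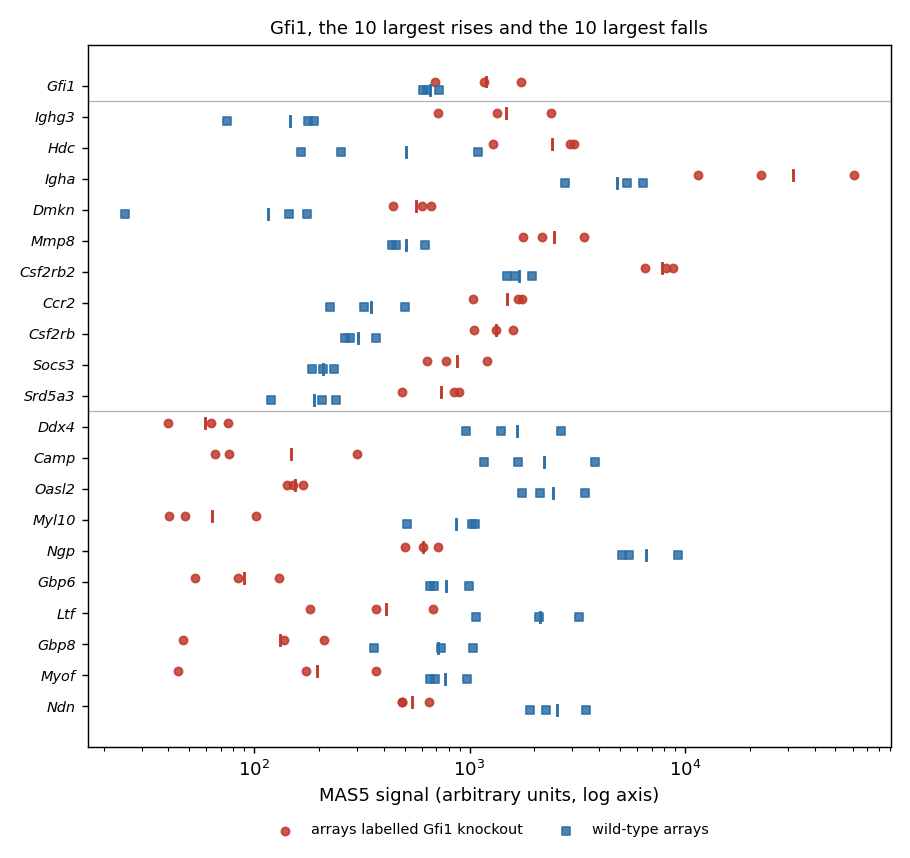
MAS5 signal of Gfi1, the 10 genes with the largest rise and the 10 with the largest fall, on a log axis, 1 point per array and a vertical bar at each group's mean (n = 3 each), circles for arrays labelled Gfi1 knockout and squares for wild type. The groups do not overlap for the 20 changed genes, such as Ngp at means of 608 and 6627, while the Gfi1 signals overlap, at 692 to 1737 and 608 to 723.

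In all, 196 probe sets were higher and 297 lower in the knockout-labelled arrays at an adjusted p under 0.05, which is 3.63% of the 13575 tested and covers 151 and 229 named genes. At an unadjusted p under 0.05 there were 1232 and 1429. At least 2-fold changes without overlap between the groups numbered 101 higher and 217 lower. Non-overlap itself was seen for 1618 and 1641 probe sets (11.9% and 12.1%), where chance gives 10% for both directions together with 3 against 3 arrays. With the sample number as a block the calls numbered 320 and 479, without the brightness filter 69 and 119, and with eBayes without trend 57 and 124. The counts changed with single arrays left out: the higher calls numbered 102, 66 and 34 without knockout 5, 7 and 8 and 126 and 64 without wild type 5 and 7, and the lower calls 184, 131 and 100 without knockout 5, 7 and 8 and 90 without wild type 7. Without wild type 8 there were 266 higher and 282 lower calls. A fit with fewer arrays has less power, so a call lost in it need not rest on the array left out. The 2-fold rises numbered 188 without wild type 8.

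Granulocyte-monocyte progenitor genes were the list with the most rises. Of 27 tested members 12 rose and 0 fell (16 and 0 adjusted over the list alone), 24 lay above 0, and the median difference was 0.86. Besides Csf2rb2 and Csf2rb, Anxa3 rose by 1.61 ± 0.20 and Ap3s1 by 1.39 ± 0.21. Mpo, the peroxidase of primary granules, rose by 0.93 ± 0.21, from 16168 ± 6255 to 29570 ± 2616 (SD, n = 3 each), and Csf1r, the M-CSF receptor, by 0.69 ± 0.17. Elane, neutrophil elastase, stood at 1.22 ± 0.48 (adjusted p = 0.175), and at 2.01 with an adjusted p of 0.000907 without wild type 8 (0.000907 to 0.481 over its alternatives). The list was shifted higher by camera (adjusted p = 4.92e-12; adjusted p = 0.126 with an estimated correlation). With 1 array left out, Mpo passed only without wild type 8 and Csf1r only without wild type 7 (adjusted p up to 0.120 and 0.153 otherwise). Csf1r also fell short with median centring, quantile and cyclic loess normalization (0.0528, 0.0549 and 0.0630), while its dimmer probe sets rose by 1.13 ± 0.22 and 1.11 ± 0.21.

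Markers of mature myeloid cells moved in both directions in the same arrays as these genes and as the lists that follow. Of 21 tested monocyte and macrophage markers 4 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.51. They were Ccr2, Ms4a6c at 1.35 ± 0.22, Ccl6 at 1.36 ± 0.28 and Csf1r, which the progenitor list also holds (camera adjusted p = 8.09e-06; adjusted p = 0.126 with an estimated correlation). Of 12 tested neutrophil markers 5 fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -1.05. With the sample number as a block 7 fell, Cd177 (-1.08 ± 0.32, adjusted p = 0.0867, blocked 0.0342) and Mmp9 (-1.02 ± 0.32, adjusted p = 0.0944, blocked 0.0347) being the 2 added, both chosen after their values were seen. S100a8 and S100a9, chosen after their values were seen, fell by 1.39 ± 0.36 and by 1.84 ± 0.38 with Ngp, Camp and Ltf, and Mmp8 rose (camera adjusted p = 1.86e-05; adjusted p = 0.312 with an estimated correlation). Without single arrays the calls of Ccl6 (knockout 5, knockout 8 or wild type 7) and of S100a8 and S100a9 (knockout 7, knockout 8, wild type 5 or wild type 7) were lost, with adjusted p up to 0.0870, 0.208 and 0.103. S100a8, whose groups overlapped, also fell short with median centring, quantile and cyclic loess normalization (0.0547, 0.0561 and 0.0550).

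Lymphoid priming genes were lower as a group. Of 18 tested members 9 fell and 0 rose (14 and 0 adjusted over the list alone), all 18 lay below 0, and the median was -0.94. These counts take the brightest probe set of each gene, which for Ighm stood at -0.16 ± 0.17. Dimmer Ighm probe sets, chosen after their values were seen, rose by 1.56 ± 0.24 and 2.35 ± 0.45 (adjusted p = 0.00321 and 0.0141). The second of these was lost without knockout 5 or knockout 8. Il7r, the interleukin-7 receptor, fell by 1.97 ± 0.28, from 2230 ± 796 to 542 ± 142 (SD, n = 3 each), Flt3, a receptor of lymphoid-primed progenitors, fell by 1.19 ± 0.19, Gimap6 fell by 1.32 ± 0.19 and Satb1, a chromatin organiser, fell by 1.08 ± 0.18. These 4 passed with any 1 array left out. camera gave an adjusted p of 3.81e-12, and the adjusted p was 0.126 with an estimated correlation. In the same arrays the neutrophil and monocyte marker lists had medians of -1.05 and 0.51.

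Stem cell genes were lower too, with 5 of 20 tested members down and 0 up (10 and 1 adjusted over the list alone, and 6 and 1 with the sample number as a block, where Thy1 at 0.82 ± 0.24 passed with 0.0431 against 0.0785) and a median of -0.56. Hlf, a transcription factor of stem cells, fell by 1.26 ± 0.19, Ndn fell by 2.17 ± 0.24, Mycn fell by 0.75 ± 0.18, Gimap1 fell by 0.91 ± 0.22, and Kit, the receptor for stem cell factor by which the cells were sorted, fell by 0.71 ± 0.17 (camera adjusted p = 0.000281; adjusted p = 0.126 with an estimated correlation). Hlf and Ndn passed with any 1 array left out, Mycn with none, Gimap1 only without knockout 5 and Kit only without wild type 5 (adjusted p up to 0.104, 0.138 and 0.132), and with median centring these 3 did not pass (0.0972, 0.0623 and 0.103). Of the 7 tested HoxA genes and cofactors 1 fell and 0 rose (3 and 0 adjusted over the list alone, and 2 and 0 with the sample number as a block), Hoxa5 by a difference of -1.05 ± 0.25. Hoxa9 stood at -0.50 ± 0.13 (adjusted p = 0.0594, and 0.0295 with the sample number as a block), its dimmer probe set at -0.02, and Meis1 at -0.36 ± 0.17 (0.255). That list's median was -0.36 (camera adjusted p = 0.0413; adjusted p = 0.312 with an estimated correlation). Its call was lost without knockout 7, knockout 8, wild type 7 or wild type 8 (0.0650, 0.0853, 0.0779 and 0.0529), and so was that of Hoxa5 (adjusted p up to 0.162).

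Genes on the list of cell cycle inhibitors were lower, and DNA replication genes lay slightly higher. Of 21 tested cell cycle inhibitors and quiescence regulators 5 fell and 0 rose (9 and 0 adjusted over the list alone, and 9 and 0 with the sample number as a block), with a median of -0.54. Ccng2, an atypical cyclin linked to growth arrest, fell by 1.49 ± 0.17, Nr4a1 fell by 1.12 ± 0.15, Tob1, an antiproliferative gene, fell by 1.41 ± 0.26, and Ndn and Egr1 made up the 5. Cdkn1a, which encodes the inhibitor p21, stood at -0.21 ± 0.24 (adjusted p = 0.687). The list was shifted lower by camera (adjusted p = 8.14e-07; adjusted p = 0.126 with an estimated correlation). Tob1 was lost without knockout 8 (0.0533). Among 43 S phase genes 0 passed in limma (14 higher and 1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone), while with the sample number as a block 1 did, Lig1 at 0.47 (adjusted p = 0.124, blocked 0.0424), chosen after its values were seen. Of the 43, 34 lay above 0 and the median was 0.25 (camera adjusted p = 0.000275; adjusted p = 0.126 with an estimated correlation), with Cdc6 at 0.67 ± 0.22 (adjusted p = 0.104). Dimmer probe sets of 2 genes, Rrm2 at 1.28 ± 0.24 (adjusted p = 0.0129, and 0.0556 without knockout 7) and the G2 and M phase gene Kif23 at -1.45 ± 0.27 (0.0104, and 0.0588 without wild type 7), did pass and were chosen after their values were seen. Among 42 G2 and M phase genes 0 passed (1 higher and 3 lower at an unadjusted p under 0.05, 0 adjusted over the list alone) and the median was 0.06, or 0.13 without wild type 5 and -0.01 without wild type 7 (camera adjusted p = 0.392).

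Immediate early genes, which cell handling can induce, were also lower. Of 26 tested members 4 fell and 0 rose (5 and 0 adjusted over the list alone, and 7 and 0 with the sample number as a block). The 4 were Nr4a1, Ier2 (-1.03 ± 0.16), Egr1 (-1.12 ± 0.22) and Dusp2 (-0.81 ± 0.21). The median was -0.48, and -0.77, -0.32, -0.31 and -0.23 without knockout 5, knockout 7, knockout 8 and wild type 5. Nr4a1, Egr1, Klf4 (-0.71 ± 0.38, adjusted p = 0.340, blocked 0.0382) and Btg2 are also on the list of cell cycle inhibitors, whose remaining 17 members had a median of -0.48 and a camera adjusted p of 0.000107, an alternative added after the data were seen. The immediate early list had a camera adjusted p of 0.000128 (adjusted p = 0.336 with an estimated correlation). The call of Egr1 was lost without knockout 7, knockout 8 or wild type 7 (adjusted p up to 0.0923), and with 1 array left out Dusp2 passed only without wild type 5 (up to 0.204 otherwise). Dusp2 also did not pass with median centring, quantile or cyclic loess normalization (up to 0.0788).

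Interferon-response genes were lower as a list. Of 31 tested members 6 fell and 1 rose (14 and 1 adjusted over the list alone), and the median was -0.48. Besides Oasl2 and Gbp6, Iigp1, an interferon-inducible GTPase, fell by 1.67 ± 0.20, while Ifitm1, a membrane protein that restricts viral entry, rose by 1.14 ± 0.16. These 4 passed with any 1 array left out (camera adjusted p = 1.77e-07; adjusted p = 0.222 with an estimated correlation). Among 25 tested p53 target genes 3 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -0.21, or -0.11 without wild type 5: Plk2 (-1.96 ± 0.30), Trp53inp1 (-1.13 ± 0.23) and Sesn1 (-0.74 ± 0.17), while Mdm2 stood at -0.99 ± 0.29 (adjusted p = 0.0775, and 0.00929 with the sample number as a block). The p53 list had a camera adjusted p of 0.0358 (adjusted p = 0.242 with an estimated correlation), which became 0.0564 without knockout 8, 0.0779 without wild type 7, and 0.0663 over the 22 members on none of the interferon, immediate early and cell cycle inhibitor lists, an alternative added after the data were seen. Trp53inp1 was lost without knockout 7, knockout 8 or wild type 7, and Sesn1 without knockout 5, knockout 8, wild type 5 or wild type 7 (adjusted p up to 0.0792 and 0.143).

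Genes of cell death and survival differed little one by one. Of 24 tested pro-apoptotic genes 1 rose and 0 fell (2 and 0 adjusted over the list alone, and 2 and 0 with the sample number as a block, where Cycs at 0.63 ± 0.18 passed with 0.0474 against 0.0727). The median was 0.11, and 0.22, 0.18 and 0.17 without knockout 5, wild type 7 and wild type 8, 0.17 with median centring, 0.01 without the brightness filter and 0.03 without the less specific probe sets. The gene called without the block was Aifm1, a mitochondrial flavoprotein needed for respiration that can act in cell death, at 0.68 ± 0.17, and with 1 array left out it passed only without wild type 8 (adjusted p up to 0.178 otherwise). It did not pass with median centring or cyclic loess (0.0711 and 0.0501). The list's camera adjusted p was 0.0443 (adjusted p = 0.222 with an estimated correlation), and its call was lost without knockout 7, knockout 8, wild type 5 or wild type 8 (0.0650, 0.0853, 0.0797 and 0.0614). Among 23 anti-apoptotic genes 0 passed (1 higher and 4 lower at an unadjusted p under 0.05, 0 adjusted over the list alone), while with the sample number as a block 2 did, Birc2 at -0.72 ± 0.20 (adjusted p = 0.0615, blocked 0.0277) and Xiap at -0.68 ± 0.21 (adjusted p = 0.0931, blocked 0.0482), and the median was 0.22, or 0.13 without knockout 5 (camera adjusted p = 0.363). Dimmer probe sets of Xiap and Mcl1, chosen after their values were seen, passed without the block, at -0.70 ± 0.18 and -0.51 ± 0.13 (adjusted p = 0.0490 each), and both were lost whichever array was left out, knockout 5, 7 or 8 or wild type 5, 7 or 8 (up to 0.197 and 0.162). Bcl2 stood at 0.13 ± 0.25 (adjusted p = 0.834), and Bax was not analysed here. Of 58 oxidative phosphorylation genes 56 lay above 0, with a median of 0.34, and 1 passed, Atp5o at 0.65 ± 0.17 (adjusted p = 0.04999, 0 adjusted over the list alone). With the sample number as a block 7 rose, among them Cycs, Ndufa8 at 0.55 ± 0.16 (adjusted p = 0.0775, blocked 0.0438) and Atp5g1 at 1.11 ± 0.32 (adjusted p = 0.0775, blocked 0.0482). The list's camera adjusted p was 6.76e-12 (adjusted p = 0.289 with an estimated correlation), and with 1 array left out Atp5o passed only without wild type 8 (adjusted p up to 0.199 otherwise). It did not pass with median centring, quantile or cyclic loess normalization (up to 0.0743). Dimmer probe sets of Ndufb9 and Ndufv2, chosen after their values were seen, passed at 0.88 ± 0.23 and 0.61 ± 0.16 (adjusted p = 0.0476 and 0.0493). With 1 array left out Ndufb9 passed only without knockout 7 (up to 0.183 otherwise), and Ndufv2 was lost whichever array was left out (up to 0.209). The Gapdh control probe set at the 3' end was also brighter on the knockout-labelled arrays, at 15421 ± 909 against 11214 ± 689 (SD, n = 3 each). The AFFX control probe sets for Cre (3' end) and BioB (middle) were dimmer there, with overlapping ranges. They stood at 13956 ± 2554 against 18327 ± 1787 and at 626 ± 95.5 against 705 ± 77.4.

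Genes described as repressed by Gfi1 and megakaryocyte-erythroid genes were not shifted by camera. Of 16 tested genes described as repressed by Gfi1, 2 rose and 1 fell (2 and 2 adjusted over the list alone, and 2 and 2 with the sample number as a block, Hoxa9 being added), and the median was -0.19, or -0.09 without knockout 7 and 0.01 without knockout 8 or without wild type 7, while the mean was 0.01 and the test pointed lower (camera adjusted p = 0.667). They were Id1, an inhibitor of helix-loop-helix factors, at 1.29 ± 0.27, Csf1r and Egr1, and Id1 was lost without knockout 5, knockout 7 or wild type 7 (adjusted p up to 0.0806). Gfi1b, the paralogue of Gfi1, stood at 0.08 ± 0.35 (adjusted p = 0.936), and the probe sets of Id2 were too dim to be tested. Among 23 megakaryocyte-erythroid genes 1 fell and 0 rose (1 and 0 adjusted over the list alone, and 2 and 0 with the sample number as a block, where Rhd at -0.90 ± 0.34 passed with 0.0492 against 0.154), Car2, a carbonic anhydrase, by a difference of -1.73 ± 0.19, and the list's median was -0.02 (camera adjusted p = 0.232, and 0.0179 without wild type 5). That median was -0.04, -0.09 and -0.09 without knockout 5, 7 and 8 and -0.17, -0.20 and 0.01 without wild type 5, 7 and 8, and it was -0.21 in the brighter 40% and 0.04 with median centring. Gata1 stood at 0.00 ± 0.23 (adjusted p = 0.997) and Epor at 0.05 ± 0.25 (adjusted p = 0.947).

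**Figure D3:**
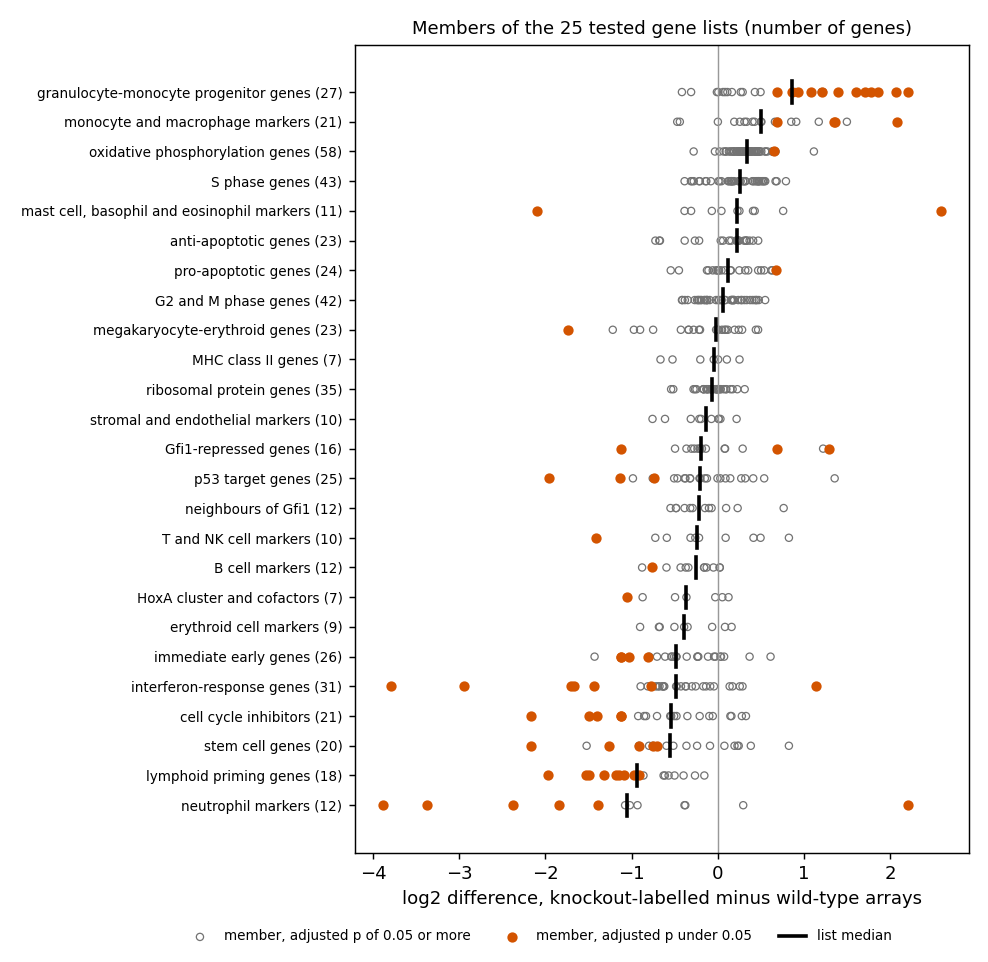
Log2 difference, knockout-labelled minus wild-type arrays, of each tested member of the 25 tested gene lists, 1 point per gene, filled where the limma adjusted p was under 0.05, with a bar at the list's median and the number of genes in brackets. Medians run from -1.05 for neutrophil markers and -0.94 for lymphoid priming genes to 0.86 for granulocyte-monocyte progenitor genes.

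Over the 25 lists, camera with the preset correlation called 14, 5 higher and 9 lower. With an estimated correlation it called 0, with 6 lists at an unadjusted p under 0.05, and fry called 7. The estimates ran from -0.038 (stem cell genes) to 0.550 (neutrophil markers), against the preset 0.01. Stem cell genes and cell cycle inhibitors (0.011) lost their calls too, with camera p of 0.0135 and 0.00652 before adjustment. For these 2 lists a higher correlation does not account for the loss. With an estimated correlation, camera also takes its degrees of freedom from the 6 arrays and not from the genes. That raises p at the same shift. For the other lists the effects of correlation and of degrees of freedom were not separated. Other splits of the same 6 arrays gave up to 13 called lists, but they keep part of the group difference and are no measure of chance.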

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

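Alternatives that leave out members shared between lists, members on the chromosome of Gfi1, or Mmp8 were chosen after the data were seen. Over the alternatives the named genes kept their side of the threshold 1729 times, fell below it 162 times and rose above it 40 times. The sign of the difference changed 11 times, in 5 genes (Cdkn1a, Gata1, Epor, Gfi1b and H2-Ab1), and in 0 of these was the gene called in either fit, while 104 of the 493 calls were kept whichever single array was left out. Of 39 called probe sets of genes named beyond the 20 largest changes, 21 were lost without the brightness filter, 19 with eBayes without trend and 22 in at least 1 fit with an array left out, with adjusted p up to 0.143, 0.134 and 0.208. Where no cause is given below, the cause was not tested. Probe sets at the level of the Bacillus controls have only a bound, and none of the scalings moved the median difference of all tested probe sets by over 0.1.

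Against 196 higher and 297 lower calls, there were 69 and 119 without the brightness filter, 57 and 124 with eBayes without trend, 127 higher without less specific probe sets (fewer probe sets tested) and 193 lower with median centring. With the sample number as a replicate block there were 320 and 479, which held 491 of the 493. Beyond the results printed with a blocked value, the block changed no other call of a named gene or list. Leaving out 1 array at a time gave 34 to 266 higher and 90 to 282 lower calls. At least 2-fold changes without overlap (101 higher and 217 lower) numbered 236 and 434 without the filter, 62 and 128 in the brighter 40%, 65 higher without less specific probe sets, and 104 to 188 higher with 1 array left out. The Gfi1 difference ranged from 0.45 to 1.10 with 1 array left out.

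Of the 14 list calls, 0 held with an estimated correlation and 7 with fry, and 10 to 16 lists were called with 1 array left out. The adjusted p with an estimated correlation was 0.126 for stem cell, lymphoid priming, granulocyte-monocyte progenitor, monocyte, S phase and cell cycle inhibitor genes, 0.312 for HoxA and neutrophil genes, 0.462 for B cell markers, 0.222 for pro-apoptotic and interferon-response genes, 0.242 for p53 targets, 0.336 for immediate early and 0.289 for oxidative phosphorylation genes. With fry it was 0.0750 for HoxA, monocyte and p53 genes, 0.102 for neutrophil markers, 0.197 for B cell markers, 0.181 for immediate early and 0.0794 for oxidative phosphorylation genes. The B cell call was also lost without the filter (0.0644), in the brighter 40% (0.147), with quantile normalization (0.0614), without less specific probe sets (0.583) and with the mean of a gene's probe sets (0.219). The pro-apoptotic call was lost likewise (0.129, 0.104, 0.0507, 0.356 and 0.0557), and the p53 call with eBayes without trend (0.0541), without less specific probe sets (0.113) and without members shared with 3 other lists (0.0663). Erythroid markers were called with median centring (0.0457), the replicate block (0.0436) and array weights (0.0340).

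With 1 array left out, the adjusted p ran from 0.0193 to 0.0853 for HoxA genes, 0.0179 to 0.967 for megakaryocyte-erythroid genes, 0.00387 to 0.214 for B cell markers, 0.0142 to 0.222 for erythroid markers, 0.0323 to 0.0853 for pro-apoptotic genes, 0.0229 to 0.0779 for p53 targets and 0.0141 to 0.864 for ribosomal protein genes. The other list calls kept direction and side of the threshold in all 6 such fits.

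List medians that moved by over 1.5 times at other settings, beyond those printed with the list, were 0.12 (median centring), 0.04 (cyclic loess) and 0.04 (without less specific probe sets) for G2 and M phase genes, 0.14 (without less specific probe sets) for anti-apoptotic genes, and -0.32 (brighter 40%) for p53 targets. For B cell markers the median was -0.16 without the filter and in the brighter 40%, -0.13 without less specific probe sets and -0.15 with the mean of a gene's probe sets, and for T and NK cell markers -0.09 without the filter and -0.14 without less specific probe sets. Mast cell markers had 0.14 without the filter and 0.04 with the mean, stromal markers -0.08, -0.07 and -0.07 with median centring, quantile and cyclic loess normalization, and MHC class II genes -0.02 without the filter and -0.01 with quantile normalization. Ribosomal protein genes had -0.01 with median centring, -0.03 with quantile normalization and 0.01 without less specific probe sets, the neighbours of Gfi1 -0.13 without the filter, and megakaryocyte-erythroid genes -0.05 with quantile normalization, cyclic loess and array weights and 0.00 with the mean.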

Other observations

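The tests of strain DNA, of a fall of like size in interferon-response genes, of carried-over neutrophils and of carried-over monocytes were chosen only after the results concerned had been seen.

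Markers of lymphoid, erythroid, mast cell and stromal cells, which the sort should remove, gave at most 1 call per list in each direction without the block. These lists hold only 9 to 12 tested members each. That is too few to set such counts against the 3.63% of all tested probe sets that were called. Of 12 tested B cell markers 1 fell (1 adjusted over the list alone), Cd24a at -0.76 ± 0.17 (SE), and the list had a median of -0.25 (-0.14 and -0.16 without knockout 8 and wild type 5) and a camera adjusted p of 0.0440 (adjusted p = 0.462 with an estimated correlation), and of 0.109, 0.164 and 0.214 without knockout 7, knockout 8 and wild type 5. Of 10 T and NK cell markers 1 fell, Klrd1 at -1.41 ± 0.33, and with the sample number as a block Thy1 rose too, at 0.82 ± 0.24 with 0.0431 against 0.0785 (2 higher and 3 lower adjusted over the list alone, list median -0.24, or -0.14 without knockout 8, camera adjusted p = 0.574). Cd24a was lost without knockout 7, knockout 8, wild type 5 or wild type 7, and Klrd1 without knockout 5, knockout 7, knockout 8 or wild type 7 (adjusted p up to 0.139 and 0.151). The B cell list also holds Ighm, counted by its brightest probe set, and dimmer Ighm probe sets that rose are given below. Of 9 erythroid cell markers 0 passed in limma (0 higher and 3 lower at an unadjusted p under 0.05, 1 lower adjusted over the list alone), while with the sample number as a block Hemgn (-0.67 ± 0.19, adjusted p = 0.0727, blocked 0.0382) and Rhd (-0.90 ± 0.34, adjusted p = 0.154, blocked 0.0492) did. That list had a median of -0.39, or -0.65 without knockout 5, and a camera adjusted p of 0.0579, or 0.0436 with the block and 0.0142, 0.0422 and 0.0323 without knockout 5, wild type 5 and wild type 7. Of 10 stromal and endothelial markers 0 passed (0 and 1 at an unadjusted p under 0.05, 0 adjusted over the list alone, median -0.13, or -0.24 without knockout 7 and -0.06 without knockout 8, camera adjusted p = 0.391). Of 11 mast cell, basophil and eosinophil markers Hdc rose and Ccl3, a chemokine, fell by 2.10 ± 0.25, while Cpa3, the mast cell carboxypeptidase, stood at 0.76 ± 0.21 (adjusted p = 0.0603, and 0.0437 with the block). That list had 2 higher and 1 lower adjusted over the list alone, a median of 0.23, or 0.03 without wild type 7 and -0.01 without less specific probe sets, and a camera adjusted p of 0.426. Of 7 MHC class II genes 0 passed (0 and 0 at an unadjusted p under 0.05, 0 adjusted over the list alone, median -0.05, or 0.01 with median centring and -0.14, -0.13, -0.18 and -0.15 without knockout 5, knockout 8, wild type 5 and wild type 7, camera adjusted p = 0.572). Of 35 ribosomal protein genes 0 passed (0 and 2 at an unadjusted p under 0.05, 0 adjusted over the list alone), and with the block Rpl22 (-0.52 ± 0.14, adjusted p = 0.0609, blocked 0.0411) and Rplp0 (-0.54 ± 0.16, adjusted p = 0.0819, blocked 0.0320) did. A dimmer probe set of Rps24, chosen after its values were seen, passed at -1.08 ± 0.23 (adjusted p = 0.0220), and not without knockout 5, knockout 8, wild type 5 or wild type 7 (up to 0.115). The ribosomal median was -0.06 (-0.14, 0.02, 0.03 and -0.12 without knockout 5, knockout 7, wild type 5 and wild type 7), the camera adjusted p was 0.346, and the list had camera adjusted p-values of 0.0190 without knockout 5 and 0.0141 without wild type 7.

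Immunoglobulin transcripts split by probe set. Besides Ighg3 and all 3 Igha probe sets, 2 of the 6 tested Ighm probe sets rose, by 1.56 ± 0.24 and 2.35 ± 0.45 (SE), while the brightest of them stood at -0.16 ± 0.17, and Jchain, which plasma cells also make, stood at 0.02 ± 0.23 with signals of 16595 ± 5498 and 16171 ± 4255 (SD, n = 3 each). Ighm (these probe sets) and Jchain were chosen after their values were seen. The brightest Ighm probe set had signals of 43621 ± 11743 on knockout-labelled and 47643 ± 4409 on wild-type arrays (SD). Whether carried-over B cells or plasma cells account for the immunoglobulin rises was not tested, and Jchain alone does not exclude it. The Ighm rise of 2.35 was lost without knockout 5 or knockout 8 (adjusted p up to 0.0690). Xist was bright on all 6 arrays (19354 to 33700 at its brightest probe set), at -0.50 ± 0.14 (adjusted p = 0.0615, and 0.0342 with the block), with 1 of its other probe sets at -1.07 ± 0.22 (0.0202, and up to 0.101 without knockout 7, knockout 8 or wild type 7), while none of the 6 Y-linked probe sets was bright enough to be tested. Of the 12 tested genes beside Gfi1, 0 passed by their brightest probe set (1 higher and 3 lower at an unadjusted p under 0.05, 0 adjusted over the list alone, median -0.22, or -0.12 without knockout 5, camera adjusted p = 0.244). Tmed5 pointed both ways, at 0.76 ± 0.23 for its bright probe set (adjusted p = 0.0870, and 0.0446 with the block) and at -1.17 ± 0.30 for its dim one (adjusted p = 0.0456, and 0.0538 with the block). With 1 array left out the dim one passed only without wild type 8 (up to 0.209 otherwise).

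The 6 arrays give only 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 493 called probe sets and the highest other 1. It gave 318 probe sets at least 2-fold apart without overlap, and the highest other 83. It gave 14 called gene lists, and the highest other 13. In each case 1 of the 10 splits, the real one, gave as many. Of the other splits, the 3 that also part all 3 same-numbered pairs called 0 probe sets each and 11, 0 and 13 lists. Every other split sets unequal shares of the groups against each other. It thus keeps part of the group difference and adds the rest to the spread. The counts of the other splits are therefore no estimate of what chance alone gives.

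Progenitor genes of the granulocyte-monocyte lineage were higher while lymphoid priming and stem cell genes were lower by camera, though with an estimated correlation the adjusted p was 0.126 for each of these lists. Under quantile, cyclic loess and median scaling each of the 3 lists kept at least 0.891 of its median difference. The pattern thus did not depend on these choices, but this test of array scaling as the cause could hardly come out otherwise. The deposited columns were already scaled alike, and the median difference of all tested probe sets moved only from -0.009 to 0.019, 0.006 and 0.047. A single factor per array is argued against by the opposite directions of the lists. Mature monocytes carried over into the knockout sorts, which the lineage gate should remove, may account for part of the rise, and the 5 monocyte markers brightest on the wild-type arrays, Ctss, Mpeg1, Csf1r, Vcam1 and F13a1, named after their values were seen, stood at 0.51, -0.44, 0.69, 0.66 and 0.85. The 20 monocyte genes that are not on the progenitor list (1 is, Csf1r) and the 26 progenitor genes that are not monocyte markers differed in median by -0.377 (two-sided permutation p = 0.371, 100000 resamples), so an equal rise cannot be told apart from a smaller one. The loss of Gfi1, the difference the design names, stays open and was not tested separately, and Gfi1 signal itself was not lower.

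Ngp, Camp, Ltf, S100a8 and S100a9 were lower although Mmp8 and the primary granule genes Mpo, Ctsg (1.86 ± 0.34) and Prtn3 (1.21 ± 0.28) were higher, the last 2 chosen after their values were seen. Under the 3 scalings the smallest fall of the 5 genes was -1.33, that of S100a8, so the falls did not depend on these choices. The call of S100a8 ended there because its adjusted p moved from 0.0490 to between 0.0547 and 0.0561. As above, this test of array scaling could hardly come out otherwise. Falls and rises in the same arrays argue against a single factor per array. Neutrophils carried over into the wild-type sorts, which the lineage gate should remove, stay possible: the 7 other tested neutrophil markers had a median of -0.387, with Cd177 at -1.08 and Mmp9 at -1.02 (adjusted p = 0.0867 and 0.0944, blocked 0.0342 and 0.0347), Chil3 at -0.93, Lcn2 at -0.39, Wfdc21 at -0.38, Fpr2 at 0.29 and Mmp8 at 2.21. Most of the 7 lay below 0, though none fell as far as S100a8 (-1.39), the least changed of the 5 genes. Since the 5 were the called falls of this list, smaller falls among the other markers were to be expected. That gap therefore does not weigh against carried-over neutrophils. Mmp8, a part of the pattern itself, is among the 7. Loss of Gfi1, the difference the design names, stays open and was not tested. Ctsg was lost without knockout 8 (adjusted p = 0.0572) and Prtn3 without knockout 7, knockout 8, wild type 5 or wild type 7 (up to 0.150).

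Oasl2, Gbp6, Gbp8 and Myl10, 4 of the 10 largest falls, lie on chromosome 5, as Gfi1 does, 44, 7, 8 and 183 tested genes away from it. Other genes named above and called lie there too, in both directions. They are Anxa3 (1.61), Ccng2 (-1.49), Srd5a3 (1.88), Kit (-0.71) and Flt3 (-1.19), at 28, 32, 72, 74 and 260 tested genes from Gfi1. Interferon-response genes in general did not show a fall of like size: the 26 tested ones on other chromosomes had a median of -0.481 and an interquartile range of 0.568, against -2.37 for Gbp8, the least changed of Oasl2, Gbp6 and Gbp8. Since these 3 were picked for the size of their falls, a gap to the other genes was to be expected, as was that 0 of the 26 reached -2.37. The comparison therefore cannot set these 3 apart from the rest, and a smaller general fall with these 3 at its far end stays open. Strain DNA kept around Gfi1 could lower single probe sets through sequence differences, and among the 197 other genes of the nearest 100 on each side 10 were called (5.08%) against 307 of 8027 elsewhere (3.82%), an odds ratio of 1.34 with a 95% interval of 0.628 to 2.56 (Fisher's exact p = 0.347, two-sided), so with this wide an interval an excess cannot be told apart from none. Windows of 50 and of 200 genes on each side, of which only the latter reaches Myl10, gave odds ratios of 0.794 (0.160 to 2.41) and 0.840 (0.438 to 1.48), and the loss of Gfi1 stays open and untested for these genes too.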
